A study of Mus musculus with 16 samples.

How the data were processed

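Total RNA of pituitary glands dissected from mouse embryos at embryonic day 17.5 was measured on Illumina mouse expression bead arrays, 1 array per sample. The 16 samples comprised 6 Insm1 mutants, labelled Insm1 -/-, and 10 controls, labelled Insm1 +/-, on a mixed strain background. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns, and biotinylated cRNA was prepared with the Illumina TotalPrep kit. Groups and replicate numbers were taken from the sample titles. The labels number the samples separately but do not say whether a sample held 1 gland or a pool, so p-values measure the spread between these samples.

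The deposited raw file holds, per the file headers, a mean bead signal intensity and a detection p-value for each of 25697 probes on each array. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. These intensities were neither background-subtracted nor normalised, as read from the values: no intensity lay at or below 0, and the array medians differed, from 96.5 to 132. The deposited detection p-value gives a probe's rank among the negative control beads of its own array. The deposited series matrix holds a second set of intensity values on a linear scale. Its columns rank the probes as the raw columns do (Spearman correlation 1), reach below 0, and share a nearly equal median (37.1), so it was read as background-subtracted and quantile-normalised; no header or label states these steps. It served as an alternative only, as log2 of the value with values under 16 set to 16.

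Signals were background-corrected with limma's nec, which takes the mean and spread of the negative controls from the detection p-values, with an offset of 16, and were then quantile-normalised and put on a log2 scale (limma 3.58.1, R 4.3.3, data.table version 1.17.8). Probes with a detection p-value under 0.01 on at least 6 of the 16 arrays were kept, which left 13813 probes. Between 12892 and 14156 probes per array passed that detection limit. For arrays, the number of samples limits the precision. A linear model with genotype as its only term was fitted to each probe by lmFit and eBayes, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. Every adjusted p for a gene comes from this limma fit.

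Probes were named through the platform annotation: 23978 carried 1 gene symbol, 0 carried several and 1719 are unnamed here. Of the named probes, 23962 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. That table was used only for names and for which genes neighbour each other. The 9682 genes tested were each represented by their probe with the highest mean over all arrays, and 799 kept probes without a symbol stayed in the fit. Of 725 called genes with several tested probes, all probes were called in the same direction for 384, 339 had a probe that was not called, and 2 had a probe called in the opposite direction. A further 185 genes were not called although another of their probes was.

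Where a probe was not above background on any array of a group, only a bound is given, as "at least" a fold. It compares the mean of the brighter group with the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value of any detected probe on that array.

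The text names Insm1, every measured pituitary hormone, the 8 largest rises and 8 largest falls among called genes by fitted change, and of each gene list with a called member the 3 members with the smallest adjusted p. Members of a count of 5 or fewer outside that rule, and any other gene said to be so, were named after their values had been seen. The 31 gene lists were written from textbook knowledge before the data were examined, as were the groups, the tests and the alternatives unless stated otherwise. The study's publication is known to have treated hormone and secretion genes, Notch pathway genes and skeletal muscle genes, so these lists are not independent of it. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list moves more than the other genes, and fry whether it moves at all.

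The slides were tested as batches. Slide 1 held 4 mutants and 4 controls, and slide 2 held 2 mutants and 6 controls, so values are also given with the slide as a block and within each slide. Other alternatives covered the background correction, the normalisation, the deposited normalised values, the filter, the variance model, array weights, covariates for Y-linked genes, erythroid genes and the position on the slide, other probes, single arrays left out, thresholds and a block by replicate number. The counts without control 10 were added after its values had been seen. On simulated data for this comparison with 13813 probes, the fit recovered 42 of 50 probes changed by 0.5 on the log2 scale, 48 of 50 changed by 1 and all 50 changed by 2; 10 of 200 calls were false. The list test called the 1 list shifted by 0.5 and 0 of the others. The simulated probes varied independently of each other, so the preset correlation was not checked, and far fewer probes were changed than were called in the data. In the data the estimated correlation was 0.41 for granule cargo genes, and 6 of the 13 called lists held with estimated correlations.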

Results

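Gene expression was measured in pituitary glands of mouse embryos labelled as homozygous mutants of Insm1, a zinc finger transcription factor of developing neuroendocrine cells, and of controls labelled heterozygous. The comparison of 6 mutants with 10 controls asks which transcripts depend on Insm1 in the gland at embryonic day 17.5. Median raw intensity ranged from 96.5 to 132 over the mutant arrays and from 102 to 122 over the control arrays. The number of probes above background ranged from 12928 to 13671 in mutants and from 12892 to 14156 in controls, so depth was similar in both groups. All levels below are log2 intensities given as mean ± SD, and changes are mutant minus control.

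The probe for Insm1 itself (ILMN_2859558) was not lower in the samples labelled mutant. The Insm1 level was 11.78 ± 0.23 (SD, n = 6) in mutants and 11.42 ± 0.18 (SD, n = 10) in controls, a rise of 0.36 (SE 0.10, limma adjusted p = 0.0134). The rise was 0.40 with the slide as a block (adjusted p = 0.00703), 0.57 on slide 2 (adjusted p = 0.0316) and 0.27 on slide 1, where it did not pass the threshold (adjusted p = 0.249). It also missed the threshold under median scaling (0.34, adjusted p = 0.0573). The files do not place the probe relative to the part of the gene altered in the mutant allele, so this signal does not check the labels, and mutant and control below mean samples so labelled.

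The first principal component held 44.8% of the variance and separated the genotypes. Mutants scored from -37.49 to -24.71 and 9 of the 10 controls from 18.19 to 26.83, while control 10 scored -2.42. The second component (12.8%) largely followed the slide, with scores from -29.44 to -0.10 on slide 2 and from -1.91 to 20.74 on slide 1. Control 10 also stood apart in single genes. Myl1, a myosin light chain of skeletal muscle, read 13.08 in it against 8.96 ± 0.19 (SD, n = 9) in the other controls. Tshb read 13.84 against 14.44 ± 0.12, whereas Gh read 15.12 against 15.22 ± 0.16. It was the only array with signal from both Xist (10.40) and the Y-linked gene Eif2s3y (11.05). Control 10 stayed in all results below, and the main counts are also given without it, a choice made after its values had been seen.

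**Figure D1:**
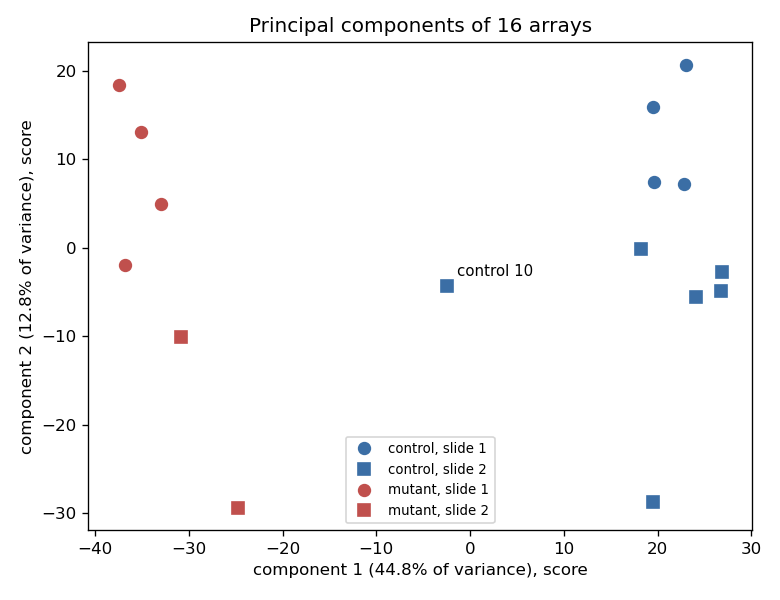
Scores of the 16 arrays on principal components 1 and 2, which held 44.8% and 12.8% of the variance of the kept probes; colour gives the genotype and symbol shape the slide. Mutants lie at or below -24.71 on component 1, 9 controls at or above 18.19, and control 10 at -2.42.

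Of 9682 genes tested, 2891 (29.9%) were called, 1540 higher and 1351 lower in mutants. Large changes were mostly falls: 271 genes fell and 103 rose at least 2-fold, and 8 fell and 3 rose at least 8-fold, with genes not above background in a whole group counted at their bound. The median absolute change of the called genes was 0.45. With the slide as a block 1528 genes were higher and 1405 lower. Within slide 1 the counts were 813 higher and 944 lower, and within slide 2, with 2 mutants, 268 and 479. Without control 10 they were 1556 and 1385. Of the genes named here by the rule, 30 missed the threshold on slide 2 alone, Hey1, Klf5, Sox9, Ccne1, Myh8 and Tyrobp among them, and 7 on slide 1 alone; all kept their direction except Ogn on slide 2. Whether more genes were higher or lower depended on the scaling, with 1250 higher and 1505 lower under cyclic loess and 1270 each under median scaling. Of the genes called lower, 88 were not above background on any mutant array, and 2 of those called higher on no control array.

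The pituitary hormones had the lowest median change of the 31 lists, though single hormones ranged from -6.75 to -1.09. Gh (growth hormone) went from 15.21 ± 0.15 in controls to 8.47 ± 1.70 in mutants, a change of -6.75 (SE 0.47, adjusted p = 9.02e-09), and ranged from 5.90 to 10.89 among the 6 mutants. Tshb (the thyrotropin beta subunit) changed by -4.25 (SE 0.14, adjusted p = 8.35e-13), Cga (the shared glycoprotein hormone alpha subunit) by -2.91 (SE 0.19, adjusted p = 5.34e-09) and Prl (prolactin) by -2.31 (SE 0.35, adjusted p = 6.51e-05). Lhb (the luteinizing hormone beta subunit) was above background on 0 mutant arrays and fell at least 4.26-fold (adjusted p = 0.000283). Prl was above background on 2 of the 6. Pomc, the precursor of corticotropin, fell least, from 13.80 ± 0.34 to 12.71 ± 0.45, a change of -1.09 (SE 0.18, adjusted p = 0.000169), and its highest mutant (13.35) lay above control 10 (13.18) and below the other 9 controls (at least 13.46).

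All 6 hormone transcripts tested fell, and also 6 adjusted over the list alone; Fshb was not above background on enough arrays to be tested. The list's median change was -3.02, or -2.61 with Lhb at its bound, and the list was shifted down by camera (adjusted p = 2.28e-08; adjusted p = 0.0130 with an estimated correlation). It is not independent of the study's publication. The median was -3.02 on slide 1 and -3.04 on slide 2. On slide 2 alone Pomc (-0.50, adjusted p = 0.269), Prl (-1.82, adjusted p = 0.0956) and Lhb (-3.01, adjusted p = 0.0913) missed the threshold.

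Receptors for releasing factors fell with the hormones. Of 8 tested, 7 fell, also 7 adjusted over the list alone, with a median of -1.84 (camera adjusted p = 2.28e-08; adjusted p = 0.0117 with an estimated correlation). Ghrhr, the receptor for growth hormone releasing hormone, read 10.58 ± 0.55 in controls and was above background on 0 mutant arrays, a fall of at least 33.0-fold (adjusted p = 8.35e-13). Ghsr, the ghrelin receptor, changed by -2.01 (SE 0.14, above background on 1 of 6 mutant arrays). Esr1, an oestrogen receptor that the list holds although oestrogen is not a releasing factor, changed by -1.98 (SE 0.21). Crhr1 changed by -0.55, which did not pass the test (adjusted p = 0.328). Without control 10 the count was again 7. The list medians within slides 1 and 2 were -1.96 and -1.48.

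**Figure D2:**
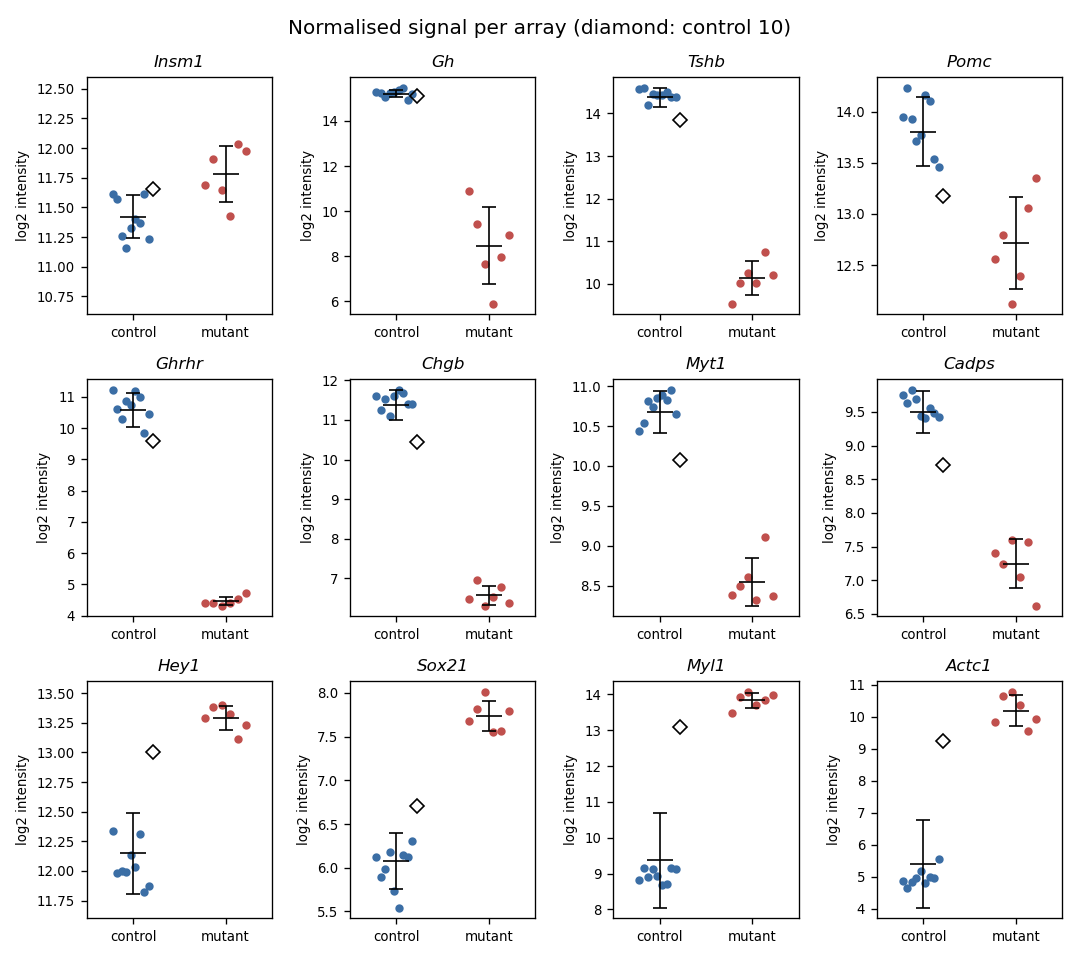
Normalised log2 intensity of 12 genes on each array, with 10 controls and 6 mutants per panel; horizontal marks and bars are the group mean and SD, and the open diamond is control 10. The vertical scale differs between panels. Gh lies between 5.90 and 10.89 in mutants and at or above 14.92 in controls, whereas Actc1 and Myl1 are high in all mutants and in control 10.

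Genes of the secretory granule fell in the same comparison. Of 12 granule cargo and prohormone processing genes tested, 11 fell, also 11 adjusted over the list alone, with a median of -2.47 (camera adjusted p = 1.14e-14; adjusted p = 0.0198 with an estimated correlation). Resp18, a granule protein of endocrine cells, changed by -4.93 (SE 0.26, adjusted p = 4.56e-10) and was above background on 4 of 6 mutant arrays. Chgb (chromogranin B) changed by -4.80 (SE 0.16) and Scg2 (secretogranin II) by -2.46 (SE 0.14). Pam, an enzyme that amidates peptides, changed by -0.30 and was not called (adjusted p = 0.367). The medians were -2.63 on slide 1 and -2.23 on slide 2. Without control 10, again 11 genes fell. Neuron markers fell in the same samples (7 of 12, median -0.46). This list and the next, on secretion, are not independent of the study's publication.

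The regulated exocytosis machinery, the proteins that dock granules and fuse them with the membrane, moved in the same direction. Of 16 tested genes 14 fell and 1 rose, with the same counts adjusted over the list alone, and the median was -0.89 (camera adjusted p = 6.01e-10; adjusted p = 0.0198 with an estimated correlation). Cadps, a priming factor of dense core granules, changed by -2.25 (SE 0.16), Sv2a, a vesicle membrane protein, by -1.71 (SE 0.13) and Sytl4 (granuphilin) by -1.17 (SE 0.095). The gene that rose was Cadps2 (0.44, adjusted p = 2.99e-05), a close relative of Cadps. Without control 10 the counts were 14 and 1. The medians were -0.93 on slide 1 and -0.82 on slide 2. Markers of neurons, which share this machinery, fell in the same samples (7 of 12, median -0.46).

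Neuroendocrine transcription factors were mostly lower. Of 10 tested, 7 fell and 1 rose, and 7 fell and 2 rose adjusted over the list alone; the median was -0.78 (camera adjusted p = 0.000677; adjusted p = 0.0198 with an estimated correlation). Myt1, a zinc finger factor, changed by -2.13 (SE 0.13, adjusted p = 3.72e-09), its relative Myt1l by -1.99 (SE 0.18, above background on 1 of 6 mutant arrays) and the basic helix-loop-helix factor Neurod4 by -1.84 (SE 0.18). The gene that rose was Hes6 (0.48). The medians within slides 1 and 2 were -0.78 and -0.80, and without control 10 again 7 fell and 1 rose. In the same samples 7 of 12 neuron markers fell (median -0.46).

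Factors that specify pituitary lineages were not shifted as a list (median -0.031, camera adjusted p = 0.508; fry adjusted p = 0.0141). Of 13 tested, 3 fell and 2 rose, and 4 fell and 2 rose adjusted over the list alone. Rxrg, a retinoid X receptor, changed by -1.74 (SE 0.15) and Gata2, a factor of thyrotropes and gonadotropes, by -0.90 (SE 0.13), while Six3 rose by 0.50 (SE 0.12, adjusted p = 0.00569). The others were Tbx19, a corticotrope factor that fell (-0.41), and Pitx1, which rose (0.46). Six3 missed the threshold within each slide, at 0.37 on slide 1 (adjusted p = 0.223) and 0.56 on slide 2 (adjusted p = 0.0504).

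Endoplasmic reticulum folding and unfolded protein response genes fell by smaller amounts. Of 20 tested, 10 fell and 0 rose, and 11 fell adjusted over the list alone; the median was -0.23 (camera adjusted p = 0.000160; adjusted p = 0.0198 with an estimated correlation). The chaperone cofactor Dnajb9 changed by -0.68 (SE 0.11), the disulfide isomerase Pdia6 by -0.47 (SE 0.080) and the stress factor Ddit3 by -0.51 (SE 0.11). Ddit3 was not called through its other probe (-0.13, adjusted p = 0.276) or on slide 1 alone (-0.45, adjusted p = 0.0814). The list medians were -0.30 on slide 1 and -0.20 on slide 2, and again 10 fell without control 10.

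Voltage-gated ion channel genes also shifted down (median -0.30, camera adjusted p = 0.00257), a call lost with an estimated correlation (adjusted p = 0.105). Of 13 tested, 7 fell and 1 rose, with the same counts adjusted over the list alone and without control 10. Kcnk3, a background potassium channel that the list holds although it is not voltage-gated, was above background on 0 mutant arrays and fell at least 3.65-fold. The calcium channel subunit Cacna1d changed by -0.68 (SE 0.087, above background on 4 of 6 mutant arrays), and the auxiliary subunit Cacna2d3 rose by 0.95 (SE 0.13, adjusted p = 1.46e-05). The median was -0.30 within each slide. Neuron markers fell in the same samples (7 of 12, median -0.46).

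Notch pathway genes shifted up (median 0.29, camera adjusted p = 0.00314), a call lost with an estimated correlation (adjusted p = 0.106). Of 23 tested, 13 rose and 3 fell, with the same counts adjusted over the list alone, and 12 rose and 3 fell without control 10. The target gene Hey1 rose from 12.15 ± 0.34 to 13.29 ± 0.10, by 1.14 (SE 0.14, adjusted p = 5.52e-06), the ligand Dll1 by 1.08 (SE 0.11) and the target Hes5 by 0.59 (SE 0.10), which was above background on 5 of 6 mutant and 1 of 10 control arrays. The genes that fell were Dtx1 (-0.50), Mfng (-0.50) and Dner (-0.40). Medians were 0.28 on slide 1 and 0.38 on slide 2. The list is not independent of the study's publication. In the same samples the medians of other cell type lists ran from -0.46 for neuron markers to 1.00 for skeletal muscle. Smooth muscle and pericytes (0.30) and macrophages (0.45) lay above the Notch median, and endothelium (0.16) and mesenchyme (0.15) below it. Notch3, which rose, is also in the pericyte list. Whether a changed share of cell types raised the Notch genes was not tested.

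Markers of pituitary progenitors were higher, with 9 of 18 tested rising and 1 falling, and 10 rising adjusted over the list alone. The median was 0.33 (camera adjusted p = 0.00314; adjusted p = 0.144 with an estimated correlation). Sox21 rose by 1.66 (SE 0.13, adjusted p = 4.73e-08), the epithelial factor Klf5 by 0.53 (SE 0.088) and Sox9, a factor of pituitary stem cells, by 0.50 (SE 0.096). Sox2, the usual marker of these cells and named here after its value was seen, changed by 0.54 and was not called (adjusted p = 0.141). The medians were 0.43 on slide 1 and 0.30 on slide 2, and without control 10 again 9 rose and 1 fell. The gene that fell was Prrx1 (-0.43). In the same samples the medians of macrophages (0.45) and of smooth muscle and pericytes (0.30) were of similar size, and those of endothelium (0.16) and mesenchyme (0.15) smaller. Whether a changed share of cell types raised the progenitor markers was not tested.

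Genes of the Wnt pathway went both ways. Of 18 tested, 5 rose and 4 fell, and 6 rose and 4 fell adjusted over the list alone (median 0.18, camera adjusted p = 0.520), and 6 rose and 4 fell without control 10. The transcription factors Tcf7l2 and Tcf7l1 rose by 0.70 (SE 0.093) and 0.79 (SE 0.11), and the Wnt antagonist Wif1 changed by -0.81 (SE 0.12). The others that rose were Lgr5 (0.63), Fzd7 (0.44) and Wnt5a (0.35), and the others that fell were Wnt4 (-0.53), Tle4 (-0.30) and Apcdd1, which was above background on 0 mutant arrays and fell at least 1.28-fold. In the hedgehog and BMP list, 2 of 11 rose and 1 fell, with the same counts adjusted over the list alone; its median and mean were below 0 and camera's direction was up (adjusted p = 0.917). The BMP antagonist Chrd changed by -0.78 (SE 0.10), and the inhibitory Smad6 and the hedgehog transducer Smo rose by 0.44 (SE 0.084) and 0.46 (SE 0.098). Smad6 was not called through its other probe (0.32, adjusted p = 0.108) or on slide 2 alone (0.33, adjusted p = 0.139).

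Genes of S and G2/M phases were lower by small amounts. Of 27 tested, 10 fell and 1 rose, and 13 fell and 1 rose adjusted over the list alone; the median was -0.21 (camera adjusted p = 0.00314; adjusted p = 0.130 with an estimated correlation). The spindle protein Nusap1 changed by -0.42 (SE 0.066) and the mitotic kinase Plk1 by -0.38 (SE 0.070), and the gene that rose was Ccne1 (cyclin E1), by 1.25 (SE 0.18, adjusted p = 4.17e-05). Without control 10, 11 fell and 1 rose. The medians were -0.24 on slide 1 and -0.17 on slide 2. On slide 2 alone Nusap1 (-0.40, adjusted p = 0.0717), Plk1 (-0.19, adjusted p = 0.299) and Ccne1 (1.11, adjusted p = 0.0745) missed the threshold.

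Skeletal muscle transcripts held the largest rises of the comparison. Actc1 (cardiac alpha actin, also used in embryonic skeletal muscle) rose by 4.78 (SE 0.52, adjusted p = 1.72e-06), Myl1 by 4.46 (SE 0.49, adjusted p = 1.85e-06) and Sln (sarcolipin, a regulator of the sarcoplasmic calcium pump, not in the list) by 4.19 (SE 0.44, adjusted p = 1.14e-06). Myh8, the perinatal myosin heavy chain, rose by 2.96 (SE 0.37), the troponin Tnnt1 by 1.84 (SE 0.18), and Myod1, the myogenic transcription factor, was above background on 0 control arrays and rose at least 1.47-fold. Above background among the controls were Actc1 on 2 arrays, Sln on 1 and Myh8 on 3. In control 10 Actc1 read 9.23, Sln 8.31 and Myh8 7.78, against means of 4.98, 4.68 and 5.14 in the other controls.

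Of 23 muscle genes tested, 14 rose and 2 fell, with the same counts adjusted over the list alone and without control 10. The list was shifted up (median 1.00, or 0.70 with Myod1 at its bound; camera adjusted p = 3.07e-06), a call lost with an estimated correlation (adjusted p = 0.101) but not without control 10 (adjusted p = 0.0440 with an estimated correlation). The genes that fell were Actn3 (-0.68, above background on 2 of 6 mutant arrays) and Atp2a1 (-0.64), a fast fibre actinin and calcium pump. Of the 23, 14 were above background on all 9 other controls, and 6 of those rose. A gene dark in most controls passed the filter only through the mutant arrays, which can raise the list's median. The median was 1.17 on slide 1 and 0.73 on slide 2. The list is not independent of the study's publication. Of the other genes among the largest rises, Msc, a repressor of myogenic factors, rose by 2.95 (SE 0.29), the epithelial factor Trp63 by 2.94 (SE 0.30, above background on 2 of 10 control arrays), the choline transporter Slc5a7 by 2.61 (SE 0.33) and the homeobox gene Gsc by 2.36 (SE 0.26).

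Ranked by fitted change, the 8 largest falls also held Dock3, a guanine nucleotide exchange factor, Cpne9, a copine, and Cwh43. Dock3 and Cpne9 were above background on 0 mutant arrays and fell at least 7.71-fold and at least 6.55-fold, bounds that leave their rank open. Cwh43 changed by -3.43 (SE 0.24) and was above background on 1 of 6 mutant arrays. Dock3 varied widely among controls (8.48 ± 1.52), and on slide 2 alone it missed the threshold (-3.60, adjusted p = 0.0830).

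**Figure D3:**
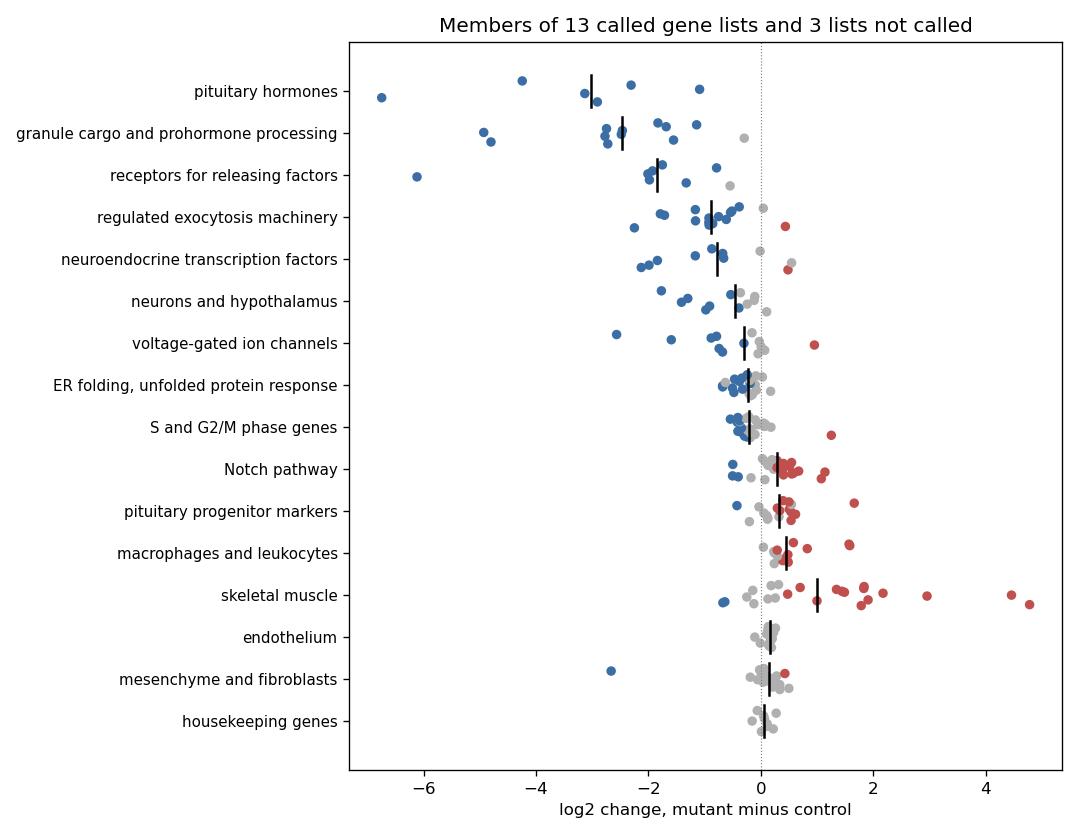
Log2 change (mutant minus control) of each tested member of the 13 gene lists shifted by camera and of 3 lists that were not; each point is a gene, coloured where called (red higher, blue lower) and grey where not, and black bars are list medians. List medians run from -3.02 for hormones to 1.00 for skeletal muscle, and no endothelial or housekeeping gene was called.

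Markers of other cell types were read in the same samples. Macrophage and leukocyte genes were higher: 10 of 15 rose and 0 fell, also 10 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.000160; adjusted p = 0.0923 with an estimated correlation). Tyrobp, an adaptor of myeloid receptors, rose by 0.58 (SE 0.10), Aif1 by 0.49 (SE 0.087) and the calcium-binding protein S100a9 by 1.57 (SE 0.28). The medians were 0.42 on slide 1 and 0.30 on slide 2, and without control 10 again 10 rose. On slide 2 alone Aif1 (0.30, adjusted p = 0.254) and Tyrobp (0.44, adjusted p = 0.0948) missed the threshold. Neuron markers were lower, with 7 of 12 falling, 9 adjusted over the list alone and 8 without control 10. The median was -0.46 (camera adjusted p = 0.000223, and adjusted p = 0.0923 with an estimated correlation). The 12 come from the neuron and hypothalamus list, whose hypothalamic hormone genes Avp, Oxt and Gnrh1 were not among those tested. Whether these transcripts came from neural tissue or from endocrine cells was not tested. The synaptic vesicle gene Syn1 changed by -1.77 (SE 0.20), the neurofilament Nefh by -1.41 (SE 0.23) and Pou4f1 by -1.30 (SE 0.17), and the latter were above background on 1 and 2 of 6 mutant arrays. The medians within slides 1 and 2 were -0.36 and -0.67.

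Of 15 endothelial genes 0 were called by limma, 1 had an unadjusted p under 0.05, and 1 rose without control 10 (median 0.16, camera adjusted p = 0.199, fry adjusted p = 0.134). The list passed camera's threshold without mutant 3 (median 0.19, adjusted p = 0.0461). Of 8 erythroid genes 0 were called and 0 had an unadjusted p under 0.05 (median 0.21, camera adjusted p = 0.520, fry adjusted p = 0.201). On slide 2 alone the erythroid list passed the threshold (median 0.30, adjusted p = 0.0420). Of 18 mesenchymal genes 1 rose and 1 fell, and 0 rose and 1 fell adjusted over the list alone (median 0.15, adjusted p = 0.656). The gene that fell was Thy1, a surface protein also present on neurons (-2.66, SE 0.25). The gene that rose was Ogn (0.43, SE 0.15, adjusted p = 0.0461), which read -0.037 on slide 2 alone and missed the threshold in 10 of the 16 fits that left out 1 array. Igf2 changed by 0.18 and was not called (adjusted p = 0.145). Smooth muscle and pericyte genes rose in 3 of 8 cases (median 0.30, adjusted p = 0.132): Acta2 by 1.51 (SE 0.36), Des by 0.67 (SE 0.14) and Notch3 by 0.55 (SE 0.12). The other 5, Pdgfrb, Kcnj8, Rgs5, Abcc9 and Cspg4, were not called. Whether the 3 rises came from these cell types or from skeletal muscle, whose list rose most, was not tested. On slide 2 alone Acta2 (1.09, adjusted p = 0.213), Des (0.38, adjusted p = 0.205) and Notch3 (0.54, adjusted p = 0.163) missed the threshold.

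Of 6 cartilage and bone genes 1 rose, Col2a1, by 0.81 (SE 0.16), and the list was not shifted (median 0.22, adjusted p = 0.508). Col9a2 (0.20, adjusted p = 0.233) and Sp7 (0.31, adjusted p = 0.265) were not called. Of 9 genes of pituicytes and glia 2 rose and 1 fell (median 0.065, adjusted p = 0.656). Aqp4, a water channel, rose by 1.17 (SE 0.16) and the glutamate transporter Slc1a3 by 0.34 (SE 0.087), whereas Mbp (myelin basic protein) changed by -0.32 (SE 0.094) through its brighter probe and by 0.090 through the other. Slc1a3 (adjusted p = 0.0531 and 0.269) and Mbp (adjusted p = 0.0760 and 0.0802) missed the threshold within slides 1 and 2, and Mbp also with erythroid genes as a covariate (adjusted p = 0.0505). In the oral and pharyngeal epithelium list 1 of 4 rose, Trp63, and 1 fell, the basal keratin Krt14 (-1.27, SE 0.20); the median was 0.0040 (adjusted p = 0.917). For these smaller lists the counts were the same adjusted over the list alone.

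Genes that flank Insm1 on chromosome 2 were not shifted as a list (median 0.034, mean -0.082, camera's direction down, adjusted p = 0.726). Of 26 tested, 3 rose and 5 fell, with the same counts adjusted over the list alone. Snx5, a sorting nexin, was above background on 0 mutant arrays and fell at least 2.48-fold (adjusted p = 7.20e-07), and the splicing factor Crnkl1 changed by -0.80 (SE 0.10, adjusted p = 8.44e-06). Ovol2 rose by 0.68 (SE 0.12) through its brighter probe and fell by 0.96 through its other tested probe, so it has no settled direction. The others were Acss1 (0.41) and Rin2 (0.35), which rose, and Nkx2-2 (-0.66, above background on 1 of 6 mutant arrays), Napb (-0.43) and Naa20 (-0.33), which fell. Of 9 housekeeping genes 0 were called by limma and 2 had an unadjusted p under 0.05, 1 of them higher (median 0.063, camera adjusted p = 0.645, fry adjusted p = 0.0209).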

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

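The tests of control 10, of the muscle genes and of the genes beside Insm1 were all chosen after those results were seen; only the test of other groupings was planned. Among 100 groupings of the 16 arrays into 6 and 10, the real one included, 1 gave 2891 or more called genes, and that was the real one. The highest of the others, which kept 5 of the 6 mutants together, gave 1423. Another, with 0 mutants in the group of 6, gave 780. The real grouping alone reached its count, so the share for chance is 1 in 100, the lowest that 100 groupings can give. Such groupings do not separate the genotype from the slide or from sex.

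Gaps to the rest of their group, measured as a share of the group's range, were unusually wide in 26 of 192 groups of values, 8 of 96 in mutants and 18 of 96 in controls, where chance gives about 1 in 20. Control 10 accounted for 16 of them. It lay highest among the controls for Myl1 (0.890), Sln (0.827), Actc1 (0.805), Msc (0.803), Myh8 (0.672), Trp63 (0.624), Tnnt1 (0.607), Myod1 (0.582), Hey1 (0.563), Gsc (0.523) and Gadd45g (0.519). It lay lowest for Cadps (0.626), Rxrg (0.584), Chgb (0.487), Tshb (0.481) and Kcnk3 (0.471). Control 1 lay highest for Krt10 (0.673) and control 8 lowest for Cacna1d (0.519). Among the mutants, mutant 1 lay highest for Cwh43 (0.720) and Krt14 (0.642), mutant 2 lowest for Scg2 (0.690) and Neurod4 (0.689), mutant 4 highest for Klf5 (0.700), and mutant 5 highest for Cartpt (0.722), Kcnk3 (0.644) and Myt1 (0.636).

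Over 115 rising and 324 falling genes chosen without control 10, its median share of the way from the other controls to the mutants on a linear scale was 0.427 for rising and 0.571 for falling genes. Mutants lay at 0.762 to 1.20 and 0.930 to 1.06 and the other controls at -0.0295 to 0.0325 and -0.0858 to 0.171, which argues against a mutant sample with a wrong label. Its 13773 detected probes (others 12892 to 14156) and its median intensity of 113 argue against a failed array. A mixture of mutant and control RNA may explain the position, but the shares only restate the position for which control 10 was picked. Control 10 was the only array with both Xist and Eif2s3y. Xist read 10.40 (11.39 to 12.75 on the 7 arrays with Xist alone). Eif2s3y read 11.05 (11.14 to 11.77 on the 8 arrays with Eif2s3y alone). Both signals together point to RNA of both sexes and do not tell the genotypes of its sources. Among the hormones, Gh (15.12) and Lhb (5.79) lay within the range of the other controls. Tshb (13.84), Cga (13.75), Pomc (13.18) and Prl (6.59) were lower in control 10 than in any other control. No biological explanation was tested.

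Skeletal muscle genes were higher in mutants. The median deviation of all 23 muscle genes was 0.70 to 1.32 in the 6 mutants and -0.063 to 0.074 in the other 9 controls. This cannot exclude genes raised in a few mutants only, because a gene dark in controls and bright in few mutants failed the filter. Myl1 and Tnnt1 were above background on all arrays. Their lowest mutants (13.47 and 10.11) lay above their highest controls (13.08 and 9.74), so for these genes a few samples did not carry the rise. A smaller share of endocrine cells would raise all other cell types alike. The muscle median exceeded that of 7 of 9 other cell type lists on every mutant by more than on any of the other 9 controls. Endothelium and mesenchyme were among the 7, and cartilage and erythroid cells were the exceptions. This cannot decide the question, because muscle genes dark in most controls passed the filter only if they were bright in mutants. Of the 23 muscle genes, 14 were above background on all 9 other controls, and 6 of those rose. The form of this test was changed after earlier forms were seen. Against the highest of the 9 lists, mutant 5 (-0.15) lay no higher than the controls (at most -0.10). Muscle tissue carried over in dissection cannot be told apart from expression in the gland. Across the 6 mutants the rises had a median pairwise Spearman correlation of 0.486, between the bounds of 0 and 0.5 set for it. Of 91 gene pairs, 80 correlated above 0. Myl1 reached 13.83 in mutants, while Atp2a1 (-0.64) and Actn3 (-0.68) fell. Ttn (0.32) and Ryr1 (-0.14), named after their values were seen, were not called. Atp2a1 read 11.08 in controls, where Actc1 was above background on 2 of 10 arrays, and Actn3 was dim (5.97 in controls). The 2 falls therefore do not decide whether muscle was carried over. An effect of genotype on the gland remains open.

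Snx5 and Crnkl1 lie near Insm1 and were lower in mutants. Crnkl1 is the nearest tested gene on its side and Snx5 the 11th on its side. Sequence from the strain that carried the mutant allele might lower such genes, but 25% of the 40 nearest tested genes were called against 29.9% of the others (Fisher's exact test, p = 0.605), which neither shows nor excludes it for single genes. A sequence difference under the probe also stays open: the other Snx5 probe read lower in mutants by -0.60 but was too dim to be tested, and Crnkl1 had 1 probe. An effect of genotype on these genes was not tested separately.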

How the results depend on the processing

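The alternatives were planned, except that the counts of called list members without control 10 were chosen after its values were seen. Over the settings other than single arrays left out, 1694 of 1745 values of named genes other than Insm1 kept their direction and side of the threshold, 48 kept the direction and missed the threshold, and 3 reversed: Mbp (0.090) and Ovol2 (-0.96) through their other probe, and Ogn on slide 2 (-0.037). Of the 48, 29 arose on slide 2 and 6 on slide 1, which hold fewer arrays. Probes above background on all arrays left out 22 named genes. With single arrays left out, 1476 of 1488 kept both, 10 missed the threshold, all for Ogn, and 2 newly passed it, Hdac1 without control 2 (0.22, adjusted p = 0.0383) and without mutant 1 (0.25, adjusted p = 0.0283). For list medians 586 of 587 and 495 of 496 kept both, and 1 in each set newly passed, erythroid cells on slide 2 and endothelium without mutant 3. The Insm1 level rose by 0.31 to 0.43 with single arrays left out, and missed the threshold under median scaling (0.34, adjusted p = 0.0573) and on slide 1 (0.27, adjusted p = 0.249); the cause was not tested. Its adjusted p ranged from 0.00395 to 0.249 over all settings.

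The count of genes higher in Insm1 mutants was 902 at an adjusted p under 0.01, 373 with a fitted change of at least 1.5-fold, 813 on slide 1 and 268 on slide 2. The count of genes lower in Insm1 mutants was 623 with such a change and 479 on slide 2. The within-slide counts come from fewer arrays. With single arrays left out, 1251 to 1573 genes were higher, 1210 to 1385 lower, and 13 or 14 lists were shifted. Cyclic loess gave 1250 higher and 1505 lower, and median scaling 1270 each. Camera with an estimated correlation called 6 lists in place of 13, and 7 without control 10, skeletal muscle being the added 1. Fry called 20. All 13 lists were also called with the slide as a block and within each slide. The replicate block over 12 arrays gave 1562 higher and 1409 lower, against 1212 and 1197 for the same arrays without it. Samples of the same number correlated at 0.040 to 0.478 in their deviations, 5 of 6 pairs above 0.1, and 4 of 6 matched their own number best, a hint of shared structure. Pairing was accepted only if all 6 lay above 0.1, so it was not used; samples of the same number also lay on the same slide. Against the same arrays without it, the block ended the call of Ogn (0.54, adjusted p = 0.0563) and added that of Six3 (0.43, adjusted p = 0.0539 without it), and changed no other named gene or list. Signal over background limits the 88 genes not above it on any mutant array.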

Other observations

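Neuropeptides other than the pituitary hormones went both ways: of 7 tested, 3 fell and 2 rose, with the same counts adjusted over the list alone (median -0.28, camera adjusted p = 0.224). Cartpt and Gal (galanin) changed by -2.19 (SE 0.26) and -2.12 (SE 0.22), while Grp (gastrin-releasing peptide) rose by 1.14 (SE 0.20). The others were Nmb (-0.65), which fell, and Pdyn (0.36), which rose. Gal was above background on 3 of 6 mutant arrays, and Cartpt missed the threshold on slide 2 alone (-1.15, adjusted p = 0.0868). Single immediate early genes fell, with Fos at -1.66 (SE 0.26), Junb at -1.01 (SE 0.18) and the phosphatase gene Dusp1 at -0.53 (SE 0.11). On slide 2 alone Junb (-0.67, adjusted p = 0.183) and Dusp1 (-0.53, adjusted p = 0.112) missed the threshold. In the list of 12 immediate early and heat shock genes, 4 fell and 2 rose, also adjusted over the list alone, and the list was not shifted (median -0.085, adjusted p = 0.456). The others called were Fosb (-0.64, above background on 3 of 6 mutant arrays), Hspb1 (0.47) and Dnajb1 (0.18).

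Among cell cycle inhibitors 3 of 10 fell and 2 rose, and 4 fell adjusted over the list alone (median -0.16, adjusted p = 0.321). Gadd45g rose by 1.06 (SE 0.11) while its relative Gadd45a changed by -0.94 (SE 0.13), and the pocket protein gene Rbl1 changed by -0.48 (SE 0.064). The others called were Cdkn1c (0.35) and Rb1 (-0.49). Of 12 p53 targets and apoptosis genes 2 rose and 2 fell, also adjusted over the list alone; the median was -0.072, the mean 0.0078 and camera's direction down (adjusted p = 0.723). The pro-apoptotic genes Bcl2l11 and Pmaip1 rose by 0.45 (SE 0.070) and 0.70 (SE 0.16, above background on 2 of 10 control arrays), and Bbc3 and Sesn2 changed by -0.36 (SE 0.073) and -0.37 (SE 0.11). Among genes of the LSD1 complex, which binds the SNAG domain found in Insm1, 1 of 9 rose, Hmg20b (0.37, SE 0.084), and the list was not shifted (median 0.13, adjusted p = 0.428). Hmg20b missed the threshold within slide 1 (adjusted p = 0.0509) and slide 2 (adjusted p = 0.221). Hdac1 (0.19, adjusted p = 0.0866) and Kdm1a (-0.14, adjusted p = 0.137) were not called.

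Of Xist and 3 Y-linked genes 0 were called by limma and 0 had an unadjusted p under 0.05 (list median 0.56, camera adjusted p = 0.819, fry adjusted p = 0.387). The fit pooled both sexes, which leaves it little power for these genes (SE 1.61 for Xist). On arrays with Xist alone, Xist read 11.39 and 11.49 in mutants and 12.12 to 12.75 in controls, a difference that was not tested. Leaving control 10 aside, 2 mutant and 5 control arrays had signal from Xist alone, and 4 mutant and 4 control arrays from Eif2s3y alone.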
